A study of Homo sapiens with 8 samples.

How the data were processed

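ChIP-seq of H3K79me2 and H3K79me3 in MOLM-13 cells with shNC or shLAMP5-AS1 was deposited as 1 table of differential regions per mark. Per the labels' titles there were 8 libraries, 1 ChIP and 1 input for each mark and condition, so each group held 1 sample. Some label fields disagree with the titles: the treatment field names other knockdowns and the growth field describes a xenograft-derived culture. The titles and the cell type field were followed here.

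Per the submitters' processing notes, the tools of the authors included Bowtie2, MACS2 2.1.1, bedtools and DESeq2, and the builds named are GRCh38, hg38 and hg19. The notes used here give neither the role nor the order of these tools and builds, and the step that made the tables is not stated. Each deposited row gives a region, a name that marks it as positive or negative, a signed score made by the authors, and the authors' annotation with promoter, 2 kb upstream, exon, intron, 2 kb downstream, UTR and CpG island columns. Per the file headers the score column has no unit of its own. All score signs matched the region names (0 exceptions in either table). The sign is not defined in the files or labels, and the order of conditions in a comparison's name does not define it, so signs are reported as deposited.

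The scale of the deposited score was examined on its values. Score sizes were never under 5.08 for H3K79me2 and 5.01 for H3K79me3, and were compared with -log10 of Poisson upper-tail probabilities of whole pileups. Comparison values tried were the whole numbers up to 15 and a fitted background under 1, with a tolerance of 0.005. Such a value was found for 87.1% of negative and 92.2% of positive H3K79me2 regions and for 93.9% and 83.4% of H3K79me3 regions. Scores moved at random by up to 0.3 found one in 23.6%, 24.0%, 22.8% and 19.6%. A single solution was found for 76.1%, 76.9%, 80.7% and 58.2% of regions, and for 21.3%, 21.7%, 20.4% and 16.9% of moved scores. The fitted backgrounds were 0.766 and 0.722 for H3K79me2 and 0.711 and 0.689 for H3K79me3. On this reading, and over regions with a single solution only, the median pileup was 14 for H3K79me2 and 13 for H3K79me3. The comparison value was most often 1 or the background. It was 3 or more for 26.6% of negative and 27.1% of positive H3K79me2 regions with a single solution. For H3K79me3 these shares were 13.6% and 32.1%. A ratio of 14 to 1 has an exact 95% interval from 2.13 to 592, counting error only, so single regions are imprecise. Library depth, input signal and per-library signal were not used here, since the tables hold none.

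Region coordinates were compared with RefSeq gene bounds on GRCh38.p14. Only 16.1% of H3K79me2 and 14.9% of H3K79me3 intron regions of a single matched gene lay inside that gene's GRCh38 bounds, although 99.9% were on its chromosome. The build is therefore not GRCh38; hg19 is the other build in the notes. RefSeq was used for names and gene types only, and 98.5% of the 3665 H3K79me2 and 98.5% of the 4045 H3K79me3 gene symbols matched. Whether starts count from 0 or 1 is not stated, so positions are given as deposited.

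A region was assigned to each gene named in its promoter, exon, intron or UTR columns, and so counts for every gene it is annotated to. Shares carry 95% Wilson or exact binomial intervals, and differences of promoter shares carry 95% normal-approximation intervals over regions. For 8 gene lists chosen before the data were examined, the median over members of the per-gene median score was placed among 10000 random lists of the same size, matched in 10 bins on mean region width. The lists were MLL fusion targets, DOT1L and elongation complexes, leukemia stem cell signature, myeloid differentiation, cell cycle and apoptosis, housekeeping, non-myeloid lineage markers and the targeted locus. Overlap of the marks needed at least 1 bp (bedtools 2.31.1). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 1.

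The design fixed beforehand assumed a fold change per region, which the tables do not hold, so the size of the score was used to rank. Named genes followed a rule fixed beforehand: for each mark and sign, the 10 protein-coding genes with the largest score size in a promoter or gene body; LAMP5, LAMP5-AS1, HOXA9, HOXA10, MEIS1 and DOT1L; up to 4 members per list and mark; and 10 genes with the same sign in both marks, ranked by the smaller score size. Ties at the last place were broken alphabetically, and tied genes are given beside the named ones. A member that this rule names is not reported here. Genes named for their number of regions were chosen after their values were seen.

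Alternatives were autosomes only, a single value per gene, only regions in promoters or genes, reciprocal overlap of 50% and shared gene symbols. Added after the data were seen were a score size of at least 10, merging regions of 1 sign within 5 kb, leaving out the gene with the most regions, wider gene windows, the MLL list without RUNX2 and DACH1, and other matching of random lists. The planned threshold of 0.01 on p was void, since every score lies past it if read as -log10 p. Planned settings on absolute log2 fold of at least 1, low signal, scaling, pseudocount and distance to the transcription start were not run, since they need values not used here. On simulated scores with a background of 0.7, a background of 0.7 was recovered for both marks and every single solution was right (100%). These scores were drawn from the same Poisson model that the recovery inverts. They check the procedure and not the reading of the deposited scores. A single solution was found for 90.6% of simulated scores in each mark, more than for the deposited ones. Of 100 unshifted simulated lists, 6 for H3K79me2 and 3 for H3K79me3 fell outside the 2.5th to 97.5th percentile. All 100 of 100 shifted lists fell below the 2.5th percentile, but the shift was larger than the median score size, so smaller shifts were not tried.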

Results

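H3K79me2 and H3K79me3, the di- and trimethylated forms of lysine 79 on histone H3, were profiled by ChIP-seq in MOLM-13 cells, an acute myeloid leukemia line that carries an MLL fusion gene. DOT1L is the enzyme that writes this methylation, which lies mostly over the bodies of transcribed genes. Cells carried either shNC, the control hairpin, or shLAMP5-AS1, a hairpin named for the long noncoding RNA transcribed antisense to LAMP5. For each mark and each condition there was 1 ChIP library and 1 input library, which makes 8 libraries in all, 4 ChIP and 4 input. With no replicates, no p-value can be given for any difference between the conditions, and peaks or genes do not stand in for replicates. Intervals on shares cover counting error only, and percentiles among random gene lists describe these libraries only. The deposited values are lists of short regions called different between shNC and shLAMP5-AS1, each with a signed score from the authors. The tables analysed here hold no read totals, so the depth of each library is unknown. The sources used here do not say whether a negative score marks higher signal in shNC or in shLAMP5-AS1 cells. Signs are therefore given as deposited, and no gain or loss on knockdown is stated for any gene. Coordinates are those of the deposited tables, in a build that is not GRCh38 and for which hg19 is the other build the submitters' notes name.

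The locus of the targeted RNA itself carried differential regions in both marks. For H3K79me3, LAMP5, which encodes a lysosome-associated membrane protein, had 9 regions and LAMP5-AS1 had 8. Counted without repeats these were 13 regions, all 13 with a negative score. The region with the largest score in LAMP5-AS1 lay in an intron at chromosome 20, 9492523 to 9492598, with a score of -20.1 in the authors' deposited table. In LAMP5 the largest H3K79me3 score in the authors' deposited table was -14.6, at the promoter (9494208 to 9494372). H3K79me2 gave 3 regions at LAMP5, 1 negative and 2 positive. The negative one, intronic at 9504365 to 9504452, had a score of -25.6 in the authors' deposited table, among the largest negative values of protein-coding genes for that mark. No RNA level was measured in the files used here, so the knockdown itself is not checked by these values.

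The comparison of H3K79me3 between shNC and shLAMP5-AS1 asks where trimethylation differs when LAMP5-AS1 is targeted. Nearly every region carried the same sign. Of 13666 regions, 13329 were negative (97.5%, 95% Wilson interval 97.3 to 97.8) and 337 were positive. Negative regions covered 1320 kb and positive regions 30.9 kb. Of 4045 genes with a region in the promoter or gene body, 3814 had negative regions only, 88 had positive regions only and 143 had both. The median size of the score was 10.2 for negative and 9.66 for positive regions, and the signed median over all regions was -10.2.

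Among protein-coding genes, the largest negative H3K79me3 score in the authors' deposited table, -51.0, lay at an annotated promoter and intron of TCF4, a basic helix-loop-helix transcription factor (chromosome 18, 53253384 to 53253460). It was the only H3K79me3 region in TCF4. ZNF516, a zinc finger gene, followed with -38.0 in the authors' deposited table and had 40 regions, all negative. YTHDF3, a reader of methylated adenosine in RNA, reached -35.5 and VAPA, an endoplasmic reticulum membrane protein, -33.9 in the authors' deposited table. MEIS1, the homeobox partner of HOXA9, had -32.8 in the authors' deposited table, in an intron at chromosome 2, 66669060 to 66669248. Then came SNX5 (-31.6), DOCK8 (-30.7), GTF2I (-30.7), the chaperone CALR (-29.9) and the splicing kinase CLK1 (-29.9), again as scores of the authors' deposited table, with CWC27 and ZNF292 tied at this last score. YTHDF3 had 24 regions, VAPA 13, SNX5 11, GTF2I 11, CALR 7 and CLK1 4, all negative, while DOCK8 had 20 negative regions and 1 positive region.

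The few positive H3K79me3 regions were spread over single sites. The largest, 99.5 in the authors' deposited table, lay at the promoter of VEGFB, a vascular growth factor gene (chromosome 11, 64001863 to 64001958). The next protein-coding genes had far smaller scores in the authors' deposited table, with 22.7 for the fucosyltransferase gene FUT9, 18.8 for DOCK10 and 17.4 for RAPGEF5. LRRC8C, a subunit of an anion channel, had 16.2 and the transcription factor gene FOXP2 16.2 in the authors' deposited table. ATAD3B, STK10, SYN3, ZNF430 and ZNF93 shared the score 14.8 in the authors' deposited table. Such a score need not stand for the gene. DOCK10 and STK10 had 1 H3K79me3 region of each sign, LRRC8C had 3 of each, and ZNF430 had 3 negative regions and 1 positive region. VEGFB, FUT9, RAPGEF5, FOXP2, ATAD3B and SYN3 each had only the 1 positive region. Of the 10 largest positive regions, 8 were assigned to no gene, as were 18 of the 25 largest. They included chromosome 8, 43092830 to 43093028, with a score of 84.9, and chromosome 2, 207197321 to 207197424, with 71.0, in the authors' deposited table. Of the 715 genes with at least 5 regions of this mark, 645 had negative regions only and 1 positive regions only (90.3% with a single sign). When signs were shuffled over regions, the median was 78.2% and the highest value 81.4%, so the common sign alone gave most of that share.

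**Figure D1:**
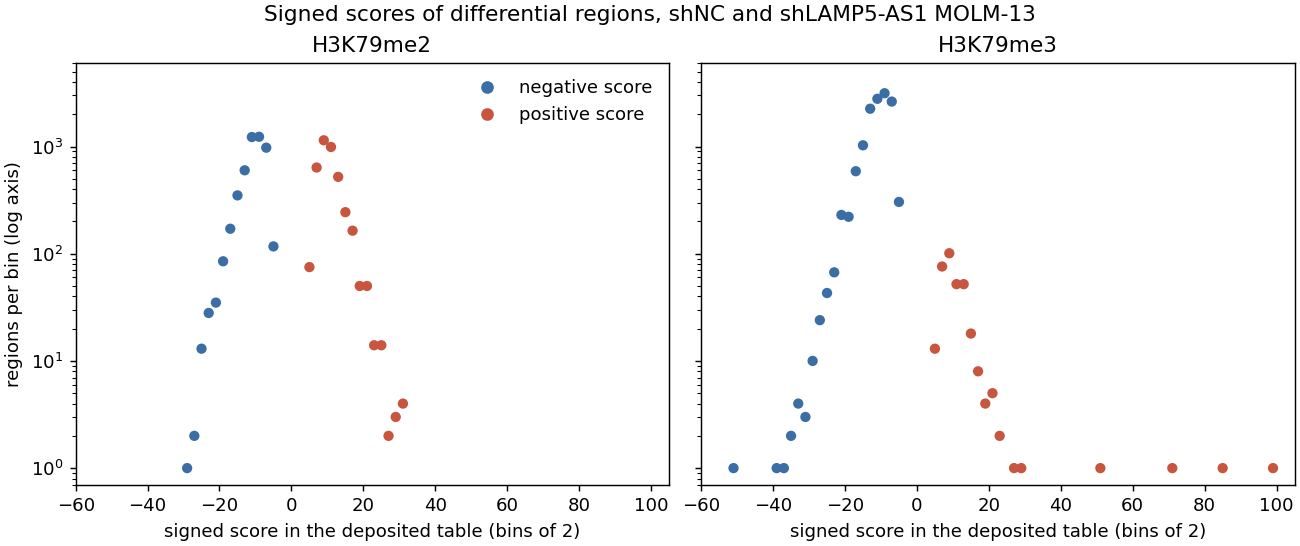
Points give the number of differential regions (vertical log axis) in score bins of width 2 (horizontal axis, the authors' signed score) for H3K79me2, left, and H3K79me3, right, with negative scores in blue and positive scores in red. H3K79me2 has 4835 negative and 3911 positive regions, while H3K79me3 has 13329 negative and 337 positive regions.

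MLL fusion targets, genes bound and kept active by MLL fusion proteins in leukemia, were among the genes richest in H3K79me3 regions. Of the 45 genes on this list, 31 had a region, 24 of them with negative regions only, 7 with both signs and 0 with positive regions only. Together they held 929 regions, 922 of them negative. DACH1, a transcriptional cofactor gene, had 147 regions and ZNF521, a zinc finger cofactor of hematopoietic progenitors, had 108, all negative. PBX3, a homeobox partner of HOX proteins, had 103 negative regions and 1 positive region, SENP6 had 76 negative regions, and the kinase gene CDK6 had 62 negative regions. JMJD1C had 62 negative regions and 1 positive region, and MEIS1 had 55 negative regions. HOXA9, the central homeobox gene of MLL leukemia, had only 2 regions, both negative, but one of them, in an exon and the 3' UTR at chromosome 7, 27202101 to 27202626, had a score of -27.6 in the authors' deposited table. HOXA10 had 1 region with a score of -8.41 in the authors' deposited table. By the largest score, the leading members after MEIS1 were JMJD1C (-28.5), HOXA9 (-27.6) and ZNF521 (-27.6) in the authors' deposited table.

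The median number of H3K79me3 regions per listed gene with a region was 14, against a median of 2 for random lists matched on mean region width, and no random list of 10000 was higher (percentile 100). The median score of the list, -10.7, was at the 22.7th percentile of random lists, so the size of the scores did not set these genes apart. Gene length was not matched, and the number of regions per gene was examined only after the values had been seen.

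For H3K79me2 the signs were divided more evenly. Of 8746 regions, 4835 were negative (55.3%, 95% Wilson interval 54.2 to 56.3) and 3911 were positive, covering 464 kb and 397 kb. Of 3665 genes, 1521 had negative regions only, 1183 positive regions only and 961 both. The median score size was 10.2 for both signs, and the signed median was -6.95. Score sizes were at least 5.08 for negative and 5.21 for positive regions, with none nearer 0. The signed median therefore mainly records which sign was the majority and is not a typical shift. H3K79me2 medians of gene lists likewise depend largely on the majority sign among a few genes.

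The largest negative H3K79me2 score of a protein-coding gene in the authors' deposited table was -27.0 for GIGYF2, a translational repressor gene, in an intron at chromosome 2, 233581279 to 233581372. USP8, a deubiquitinase gene, had -26.9 in the authors' deposited table, and AGFG1, GPATCH2L and LAMP5 each had -25.6. MED17, a subunit of the Mediator complex, had -25.5 and PPP6R3, a regulatory subunit of protein phosphatase 6, -25.4 in the authors' deposited table. KPNA1, an importin, had -24.6, while RCL1 and the splicing regulator gene CELF2 each had -24.2 in the authors' deposited table, and 5 further protein-coding genes, CPEB2 among them, tied with CELF2. On the positive side KIF5B, a kinesin heavy chain, had 31.4 in the authors' deposited table, at chromosome 10, 32337600 to 32337688, and all 4 of its regions were positive. SDC2, the cell-surface proteoglycan syndecan, had 30.1 in the authors' deposited table and 19 regions, all positive. CUX2 and MXI1, which encodes a MAX-binding repressor, had 29.0, TPD52 had 28.5 and PRICKLE1 had 27.0 in the authors' deposited table. ARFGEF2 and ENAM had 26.0, and DCLRE1C, a DNA repair nuclease, and DIAPH1, a formin, had 25.6, tied with SLC23A2, in the authors' deposited table. The largest score need not stand for the gene, since PPP6R3 had 5 positive regions beside 2 negative ones, MXI1 had 3 of each sign and CELF2 had 3 of each sign.

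Within MLL fusion targets, H3K79me2 regions went both ways. Of the 45 genes, 29 had a region, with 8 carrying negative regions only, 3 positive regions only and 18 both. The list held 166 negative and 83 positive regions (66.7% negative, against 55.3% in the whole table). RUNX2, a runt-domain transcription factor gene, had 35 regions, all negative, and DACH1 had 29 negative regions and 1 positive region. Without RUNX2 and DACH1 the list held 103 negative and 82 positive regions, 55.7% negative, close to the whole table. MEIS1 had 8 regions, all negative, the largest with a score of -21.5 in the authors' deposited table. CPEB2, with 4 negative and 2 positive regions, had the largest score of the list (-24.2 in the authors' deposited table, in an exon and the 3' UTR), and CDK6, with 6 negative regions and 1 positive region, had -21.0 in the authors' deposited table. BCL2, the inhibitor of apoptosis, went mostly the other way, with 17 positive regions and 1 negative region, as did MEF2C with 10 positive and 4 negative regions. HOXA13 had 3 positive regions, the largest with a score of 20.1 in the authors' deposited table. HOXA9, HOXA10 and DOT1L had no H3K79me2 region in a promoter or gene body. The list median of -7.69 was at the 13.9th percentile of random lists, and the median of 7 regions per gene was above every random list (percentile 100, random median 2).

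**Figure D2:**
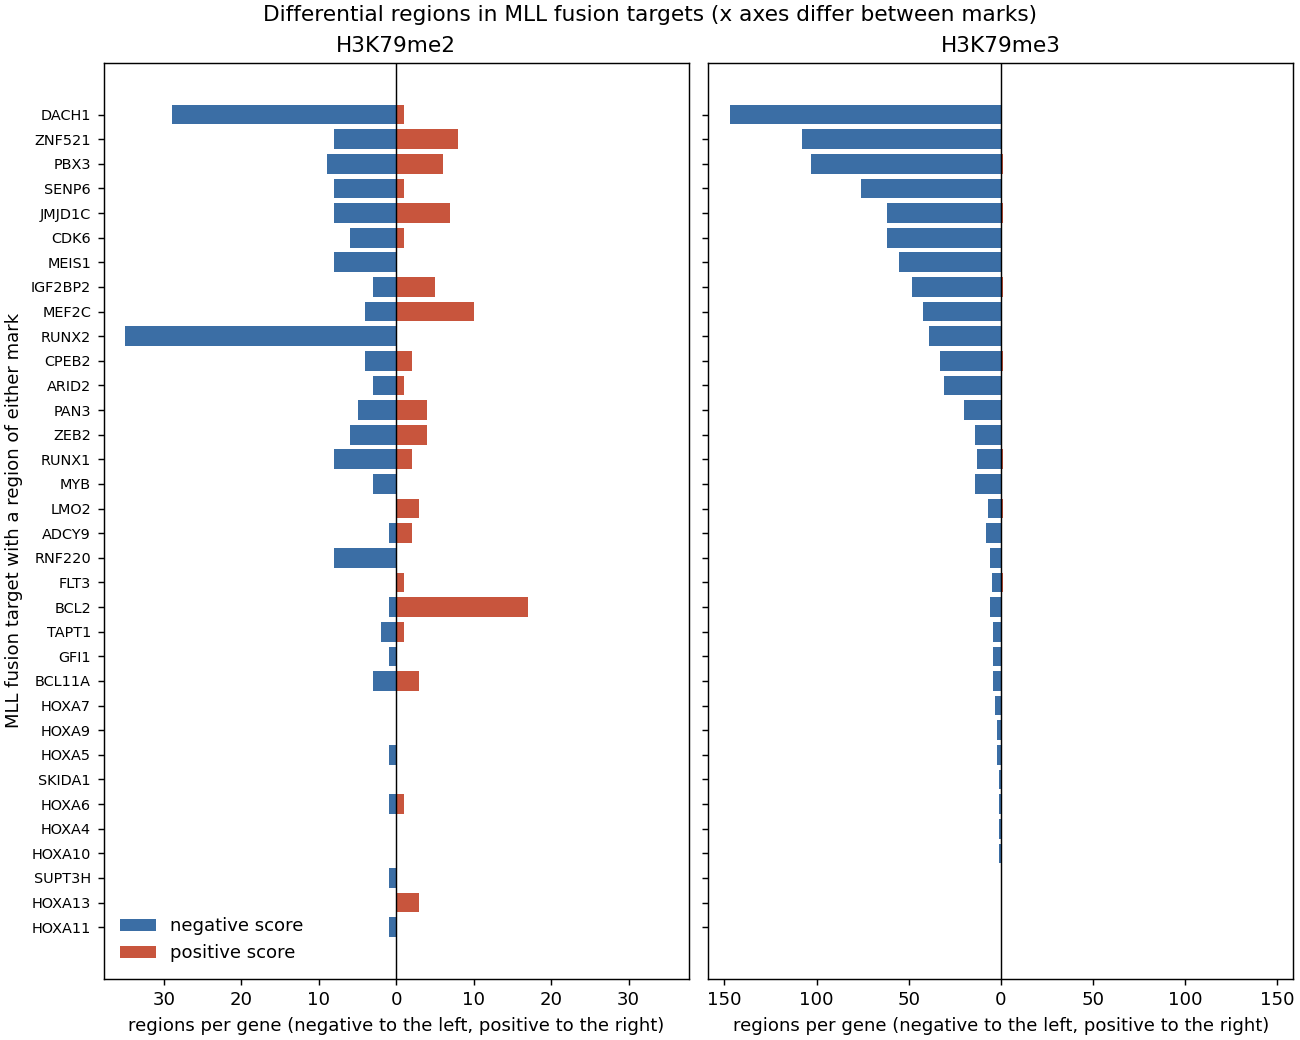
Number of differential regions per gene (horizontal axis, negative regions in blue to the left, positive regions in red to the right) for each MLL fusion target with a region of either mark, ordered by the H3K79me3 count, with separate axis ranges for H3K79me2 and H3K79me3. DACH1 leads for H3K79me3 with 147 negative regions, and RUNX2 leads for H3K79me2 with 35 negative regions, while BCL2 has 17 positive H3K79me2 regions.

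Genes of DOT1L and the elongation complexes, which couple H3K79 methylation to transcription, had regions in 16 of 31 members for H3K79me3, 83 of the 84 regions being negative. DOT1L itself had 14 negative H3K79me3 regions, the largest with a score of -21.5 in the authors' deposited table. CCNT2, a cyclin of the elongation factor P-TEFb, had -22.8 in the authors' deposited table, and CDC73 and LEO1, subunits of the PAF complex, each had -20.1. For H3K79me2, 11 of the 31 members had a region, 20 regions being negative and 27 positive. MLLT10, a DOT1L cofactor and fusion partner of MLL, had 12 positive and 4 negative regions and a largest score of 15.3 in the authors' deposited table. AFF4, the scaffold of the super elongation complex, had -15.5, MLLT1 had 14.2 and CDC73 and SUPT5H each had 13.7 in the authors' deposited table. The list medians were at the 17.6th percentile of random lists for H3K79me3 and the 69.2nd for H3K79me2.

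Myeloid differentiation genes were the list with the highest median H3K79me2 score, 8.30, at the 94.3rd percentile of random lists, inside the central 95%. Regions were found in 8 of 41 members, 5 with positive regions only, 2 with negative regions only and 1 with both, and 14 of the 19 regions were positive. LYN, a Src-family kinase gene, had 6 positive regions with a largest score of 13.2, and IRF8, a transcription factor of monocyte development, had 4 with a largest score of 12.6 in the authors' deposited table. MPO, which encodes myeloperoxidase, had a single promoter region at 13.2 in the authors' deposited table. FCGR1A, an Fc receptor gene, had 3 negative regions with a largest score of -10.2 in the authors' deposited table. For H3K79me3, 11 of the 41 genes had a region and 22 of 23 regions were negative, with the list median at the 33.4th percentile. The granule protease genes ELANE and PRTN3 had H3K79me3 scores of -23.1 and -16.0 in the authors' deposited table, CEBPD had -15.0 and CD33 had -13.7.

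Cell cycle and apoptosis genes were split for H3K79me2, with 23 negative and 27 positive regions in 17 of 40 members (list median at the 16.9th percentile), 17 of the positive regions being those of BCL2. CCNA2 (cyclin A2) had 17.1, CCND3 (cyclin D3) 16.3 and the apoptosis inhibitor XIAP 16.2 as H3K79me2 scores in the authors' deposited table, against -21.0 for CDK6. For H3K79me3, all 109 regions in 18 members were negative (60.1st percentile), led by CDK6 (-19.6), the cell cycle inhibitor CDKN1B (-18.5), MDM2 (-14.2) and, tied, BCL2 and E2F3 (-13.7) in the authors' deposited table.

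Leukemia stem cell signature genes were thinly covered. For H3K79me2 only CDK6 and LAPTM4B of 21 members had regions, 10 of 11 negative (11.3rd percentile), and LAPTM4B, a lysosomal membrane protein gene, had a largest score of -16.2 in the authors' deposited table. For H3K79me3, 4 members had 69 regions, all negative (45.1th percentile), 62 of them in CDK6. SOCS2, a suppressor of cytokine signalling, had -21.4, LAPTM4B -10.7 and ARHGAP22 -9.51 in the authors' deposited table. CDK6 belongs to 3 of the lists and BCL2 to 2, so these lists are not independent.

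Housekeeping genes carried the same H3K79me3 sign as the rest, with 53 of 54 regions negative in 17 of 25 genes (8.65th percentile). The largest scores in the authors' deposited table were those of YWHAZ (-20.8), the nucleolar protein gene NPM1 (-20.1), HSP90AB1 (-18.8) and ACTB (-16.3), and the single positive region was in SDHA. For H3K79me2, 9 of 11 regions in 8 genes were negative, and the list median of -10.4 was at the 2.44th percentile, the lowest of the lists. Of the 13 list medians placed among random lists in both marks, it was the 1 outside the central 95%. It lay just under the limit of 2.5 and rests on 8 genes. Among unshifted simulated H3K79me2 lists, 6 of 100 also fell outside, so 1 of 13 does not set this list apart. NPM1 (-18.8), YWHAZ (-17.1) and the elongation factor gene EEF2 (-16.2) had the largest H3K79me2 scores in the authors' deposited table. None of the 30 non-myeloid lineage markers had a region of either mark. For the locus of LAMP5 and LAMP5-AS1, the H3K79me3 list median was at the 38.5th percentile.

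The regions of the marks rarely coincided. Of all regions, 158 H3K79me2 and 159 H3K79me3 regions shared at least 1 bp with a region of the other mark (1.81% and 1.16%), giving 159 pairs. In 97 pairs both regions were negative and in 6 both were positive, while 52 pairs joined a positive H3K79me2 region to a negative H3K79me3 region and 4 the reverse. The same sign was found in 64.8% of pairs (Wilson interval 57.1 to 71.8), and independent signs at the shares of these pairs (101 negative for H3K79me2 and 149 for H3K79me3) would give 61.8%, inside that interval. Shifting the H3K79me2 regions by 5 kb left 137.5 pairs on average, and shifting by 100 kb left 13.5, so most of the pairs did not depend on exact positions. Across pairs, the signed scores had a Pearson correlation of 0.0389 and a Spearman correlation of 0.135, and regions are not independent replicates. At the gene level, 2080 genes had regions of both marks. Of the 1804 with a majority sign in each mark, 60.8% had the same sign, against 59.9% if independent.

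By the smaller of the scores of the marks, the genes with the largest scores of the same sign in both were all negative. This follows largely from the rarity of positive H3K79me3 regions. Of the 1804 genes with a majority sign in each mark, 1080 were negative in both and only 16 positive in both. For the genes named here, the scores of the marks come from different regions of the gene. CPEB2, with the overlapping LOC101929095, had -24.2 for H3K79me2 and -22.8 for H3K79me3 in the authors' deposited table. ESYT2, a membrane tether gene, had -21.5 in both, MEIS1 -21.5 and -32.8, and the chromatin organiser gene SATB1 -20.6 and -25.6 in the authors' deposited table. ARID1B, a subunit of the BAF remodelling complex, had -20.1 and -24.6, GNAQ, a G protein alpha subunit, -20.1 and -23.1, and HSH2D -20.1 in both, in the authors' deposited table. CDK6 had -21.0 and -19.6 and NRBF2, an autophagy factor gene, -19.6 and -22.8 in the authors' deposited table, tied with RREB1 on the smaller score. All 36 H3K79me2 regions of GNAQ were negative, as were 45 of its 46 H3K79me3 regions. In ESYT2 and ARID1B, in contrast, most H3K79me2 regions were positive, 3 of 5 and 9 of 16.

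**Figure D3:**
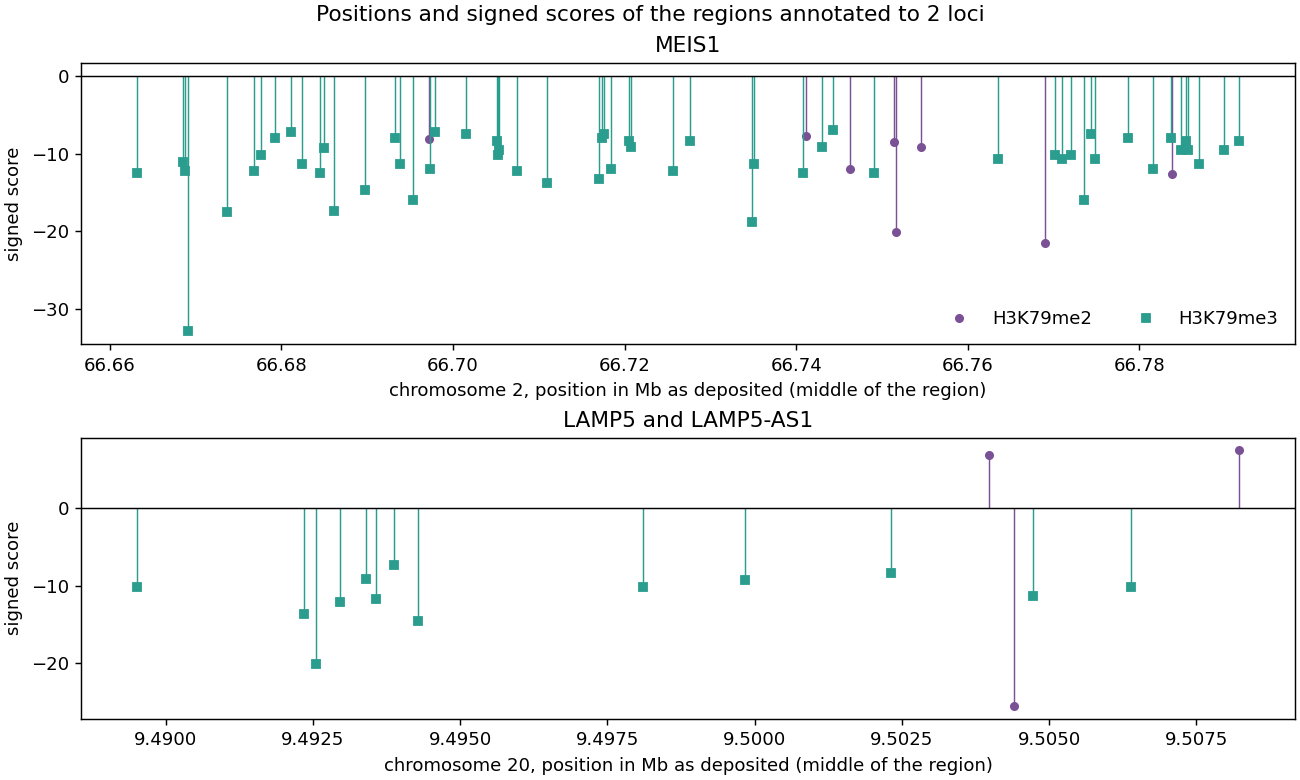
Signed score in the deposited tables (vertical axis) against the middle of each region in Mb (horizontal axis) for regions annotated to MEIS1 and to the LAMP5 and LAMP5-AS1 locus, with H3K79me2 as circles and H3K79me3 as squares. MEIS1 has 8 H3K79me2 and 55 H3K79me3 regions, all negative, and the LAMP5 locus has 13 negative H3K79me3 regions beside 3 H3K79me2 regions of both signs.

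In both marks the regions lay mainly in introns, as annotated by the authors (90.6% of H3K79me2 and 86.7% of H3K79me3 regions), and 5.55% and 8.21% lay in promoters. Negative and positive H3K79me2 regions had promoter shares of 5.42% and 5.70%, a difference of -0.283 percentage points (95% interval -1.25 to 0.684), and intron shares of 90.4% and 90.7%. CpG island shores held 10.5% of negative (Wilson interval 9.71 to 11.4) and 13.9% of positive (12.8 to 15.0) H3K79me2 regions. For H3K79me3, introns held 87.3% of negative (86.7 to 87.8) but 63.8% of positive regions (58.5 to 68.7). CpG shores held 19.1% of negative (18.5 to 19.8) and 5.64% of positive (3.64 to 8.64) H3K79me3 regions. Regions with no gene made up 7.95% (7.51 to 8.42) of the negative and 28.2% (23.7 to 33.2) of the positive ones. Promoters held 8.28% of the negative and 5.34% of the positive H3K79me3 regions, a difference of 2.94 percentage points (95% interval 0.492 to 5.39), which was 5.75 points among regions with a score size of at least 10.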

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

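In 6 genes with at least 5 regions of each mark, every H3K79me2 region was positive and every H3K79me3 region negative. They were noticed for this opposition, which was not tested, and 97.5% of all H3K79me3 regions are negative, so any gene with positive H3K79me2 regions tends toward it. FAM107B had 11 H3K79me2 and 14 H3K79me3 regions, and KMT2E, a chromatin-associated trithorax-family protein gene, had 5 and 12. PTK2B, a focal adhesion kinase family gene, had 6 of each. SLC23A2, a vitamin C transporter gene, had 6 and 5, LOC648987 had 7 of each, and C16orf72 had 5 and 7.

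The tests of the H3K79me3 sign that follow were chosen after the result was seen. A change limited to MLL fusion targets is set aside by the tables, since 93.1% of negative H3K79me3 regions lay outside the listed genes. A depth difference between the libraries could produce a single sign. The backgrounds recovered for negative and positive regions differed by a ratio of only 1.03, but which library each stands for is not stated, so depth stays open. Weaker enrichment in 1 precipitate could do the same, and 94.1% of the housekeeping genes with a region had negative regions only, as that explanation needs. A genome-wide effect of shLAMP5-AS1 would give the same value, so with 1 library per condition the explanations cannot be told apart.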

How the results depend on the processing

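Of 91 alternative values, 78 stayed within the interval or on the side of the value reported, 11 moved, 2 lost their place above the 97.5th percentile and 0 changed direction. The score minimum, merging, leaving out the gene with the most regions, wider gene windows, the MLL list without RUNX2 and DACH1 and other matching of random lists were chosen after seeing the data. With a single value per gene, the negative share of H3K79me2 was 56.3% and the H3K79me3 median score was -10.0. With only regions in promoters or genes, the negative share of H3K79me3 was 98.1%. With a score size of at least 10, it was 98.0%, the median score was -10.2 for H3K79me2 and -12.5 for H3K79me3, and the same-sign share of overlapping pairs was 76.6% (68.5% if independent at the shares of those pairs). A shift of the median follows from that setting's own construction. Merging regions of 1 sign within 5 kb gave a negative H3K79me3 share of 94.6% and a median of -10.5, since merging joins the dense negative regions. The cause of the other shifts was not tested. Of the 63 values for lists and promoter shares, 59 stayed. Most of the list values were the percent of members with mostly negative regions, which is not reported above. Its H3K79me2 intervals ran from 15.8 to 100 for the leukemia stem cell signature and from 3.67 to 71.0 for myeloid differentiation genes. Staying inside intervals this wide says little. The percentiles of list median scores had no alternative run. The negative share of H3K79me2 regions in MLL targets went from 66.7% to 55.7% without RUNX2 and DACH1. The H3K79me3 promoter difference went from 2.94 to 5.75 percentage points with a score size of at least 10. Adding the 2 kb upstream column to promoters, and autosomes only for the overlap, changed no value and tested nothing. The stricter p was void, and settings that need fold changes, per-library signal or distances were not run. Unknown depth and 1 library per group limit every value.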

Other observations

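Genes off the MLL list also held long runs of H3K79me3 regions, chosen here after their values were seen. MBNL1, a splicing regulator gene, had 106 regions, RREB1, a zinc finger transcription factor gene, had 68, FNDC3B had 62 and JARID2, a Polycomb cofactor gene, had 61, all negative. ELF1, an ETS factor gene, had 53, CNOT6L, a deadenylase gene, had 50, and the chromatin organiser gene SATB1 had 45, all negative. Of the 25 genes with the most negative H3K79me3 regions, 10 were on the MLL list.

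For H3K79me2, most genes with at least 5 regions carried both signs (307 of 410), but genes with a single sign were more frequent than with shuffled signs. Of the 410, 68 had negative regions only and 35 positive regions only (25.1%), against a median of 3.41% and a highest value of 6.10% when signs were shuffled over regions. Neighbouring regions under 1 kb apart had the same sign in 85.2% of 925 pairs, with 66.4% from 1 to 10 kb, 58.9% from 10 to 100 kb and 49.8% from 100 to 1000 kb, against 50.6% for independent signs. LIN7A had 32 and the zinc finger transcription factor gene ZBTB16 had 22 regions, all negative. On the positive side GAB2, a signalling adaptor gene, had 23 regions, LRRC8C 22, PDE7A, a phosphodiesterase gene, 21, RSRC1 21 and the homeobox gene SHOX2 11, all positive.

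A further hypothesis, also set after the data were seen, was that the marks are exchanged for one another in the same genes, which may give positive H3K79me2 beside negative H3K79me3. Positive H3K79me2 regions would then lie in genes with negative H3K79me3 regions more often than negative ones do. They did so less often, 66.0% against 76.0%, a difference of -9.97 percentage points (95% bootstrap interval over genes -15.4 to -5.51). That prediction was not met. However, 97.5% of H3K79me3 regions are negative, so the test mostly asks which genes hold any H3K79me3 region. It therefore cannot decide for or against exchange.

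The many H3K79me3 regions of MLL fusion targets might reflect gene length alone, for which 1 test was set before the result was seen and the matched versions after. The ratio of H3K79me3 to H3K79me2 regions per gene had a list median of 1.17 on the log2 scale, at the 99.96th percentile of random lists. The ratio still depends on the number of regions through the 1 added to each count, and among lists matched on region number in 10, 40 and 80 bins the percentile was 97.8, 95.6 and 89.2. Against lists matched on H3K79me2 regions, the median of 8 H3K79me3 regions was at the 100th percentile (random median 2.5), which goes against length as far as H3K79me2 regions stand in for it. The ratio was not particular to this list, with housekeeping genes at 99.9 (99.3 matched in 80 bins, 99.9 matched on H3K79me2 regions), the leukemia stem cell signature at 98.9 (94.8 and 65.6, from 4 genes) and the targeted locus at 98.8 (94.6 and 98.6, from 2 genes), and with gene lengths in this build not used here, length stays open.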
